A study of Homo sapiens with 9 samples.

How the data were processed

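RNA of HSC-3, an oral squamous carcinoma line, was sequenced as 9 messenger RNA libraries. Per the labels' protocols, RNA was extracted with Trizol and libraries were made from 1 µg of total RNA with an Illumina TruSeq RNA kit. The kit is not stranded, so overlapping genes on opposite strands cannot be told apart. Per the submitters' processing notes, CASAVA 1.8, Trimmomatic, FastQC, HISAT2, StringTie and edgeR were used with GRCh38; their order and settings, and the annotation release, were not given.

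The authors deposited a table of estimated counts for 60612 genes, whose values were whole numbers, and a table of FPKM, whose unit was inferred. For 10059 genes the ratio of deposited counts to FPKM, adjusted for the library, lay within 1% of a library constant in 49.3% of cases and within 5% in 86%. Counts of 4 were met more often than 3 or 5, and likewise for 8, 12 and 16, so 1 read pair often appeared to give 4 counts, but 1 (8706 values) was more frequent than 4 (6716) and 2 was met 4811 times. The estimated counts were used as deposited for edgeR, and the FPKM only for limma alternatives. With 4 counts taken as 1 pair, a gene near its floor was given a lower bound at 3 read pairs, that is 12 counts over a group, or an exact binomial 95% counting interval when it had 1 to 3 read pairs.

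The groups WT, MPTN24 and MPTN, with 3 libraries each, followed the sample names, and the meaning of MPTN24 and MPTN was inferred. Genes were kept by filterByExpr (minimum count 10, total 15), which left 16990. Libraries were scaled by TMM, and a single quasi-likelihood model (edgeR 4.0.16, robust, R 4.3.3) was fitted to all 9 libraries with a contrast for each of 3 comparisons. The p-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Lists were tested by camera with a preset correlation of 0.01, adjusted over the lists of a comparison. The 38 lists were fixed before the data were examined; all 1028 genes were matched, and a list needed 5 tested members. CPM are given as mean and SD of 3 libraries, with a prior count of 2 for log values in the principal component analysis.

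Named genes followed a rule fixed in advance. In each comparison these were the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM in the higher group and a gene symbol. Members of the 6 called lists with the smallest p followed, up to 4 in the list's direction and 1 in the other, and then KDR, KIT, RET, VEGFA, EGFR, AXL, ABCB1, ABCG2, MKI67, CDH1, VIM and CD274. A few genes of the lists are not reported here.

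Other settings fixed in advance were RLE size factors, upper-quartile scaling, no filter, a stricter filter (1 CPM in 3 libraries), a replicate block, each library left out, fits of only the 2 groups compared, DESeq2 1.42.0, limma 3.58.1 on log2 of FPKM plus 0.1 or plus 1, a minimum 2-fold change, camera with an estimated correlation, and fry. Added afterwards were offsets for GC content and gene length (GENCODE 29, available for 98.9% of tested genes), counts divided by 4, and list counts without WT 1 and in the settings of the list tests. Shared controls were examined with 20 simulations and 100 regroupings of the libraries.

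In a self-test, uncorrelated negative binomial counts were simulated from fitted means and dispersions, with a known fold on random genes. At 2-fold, 57.4%, 59.2% and 66.3% of the changed genes were recovered in the 3 comparisons, and at 1.5-fold 29.9%, 33.3% and 32.3%. False calls among unchanged genes were 8, 6 and 15 of 16492, 16523 and 16528 genes in the step. A shifted list was found in each comparison and 0 of 20 null lists were called. No column of values was left out.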

Results

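RNA of the human oral squamous carcinoma line HSC-3 was sequenced in 9 libraries, 3 each for the groups WT, MPTN24 and MPTN. The series describes the parental line, the line exposed to apatinib for 24 h and an apatinib-resistant line. The labels do not spell out MPTN24 and MPTN, so MPTN24 was taken as the 24 h exposure, because of its number, and MPTN as the resistant line. Apatinib inhibits the VEGF receptor KDR and, more weakly, KIT and RET. Whether the drug was present at harvest of MPTN is not stated. Total counts per library were 65227021, 69017121 and 88923424 in WT, 60383313, 65256683 and 65220502 in MPTN24, and 70969935, 75634485 and 98890929 in MPTN. A read pair often appeared to give 4 counts. Between 19947 and 21374 genes had a count in a library, and 16990 of the 60612 annotated genes had enough counts to be tested. The origin of the replicates is not stated, so every p-value here measures only the spread between samples, which may be technical. In a principal component analysis the first component held 31.4% of the variance and ordered the groups WT (-59.2 to -43.4), MPTN24 (-6.7 to -5.6) and MPTN (54.3 to 61.1). The second held 16.7% and the third, at 12.5%, set WT 1 (68.5) apart from WT 2 (-33) and WT 3 (-32.8).

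WT 1 stood apart from WT 2 and WT 3 in genes chosen here after the values were seen. FOS, a transcription factor of the immediate early response, was at 73.4 CPM in WT 1 against 718 and 693 CPM in WT 2 and WT 3, and DUSP1, a phosphatase that turns off MAP kinases, at 24.7 against 159 and 173 CPM. SCD, the desaturase that makes monounsaturated fatty acids, was at 229 against 1650 and 1430 CPM. The collagenase MMP1 was higher in WT 1, at 3590 against 923 and 974 CPM, as was the chemokine CXCL1, at 148 against 33.5 and 38.4 CPM. Mitochondrially encoded transcripts took 4.74% of counts in WT 1 against 2.72% and 3.02% in the other WT libraries, 5.04% to 5.73% in MPTN24 and 4.66% to 5.13% in MPTN. Leukocyte transcripts such as PTPRC, CD3E, TYROBP and NKG7 had 0 counts in all 9 libraries.

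**Figure D1:**
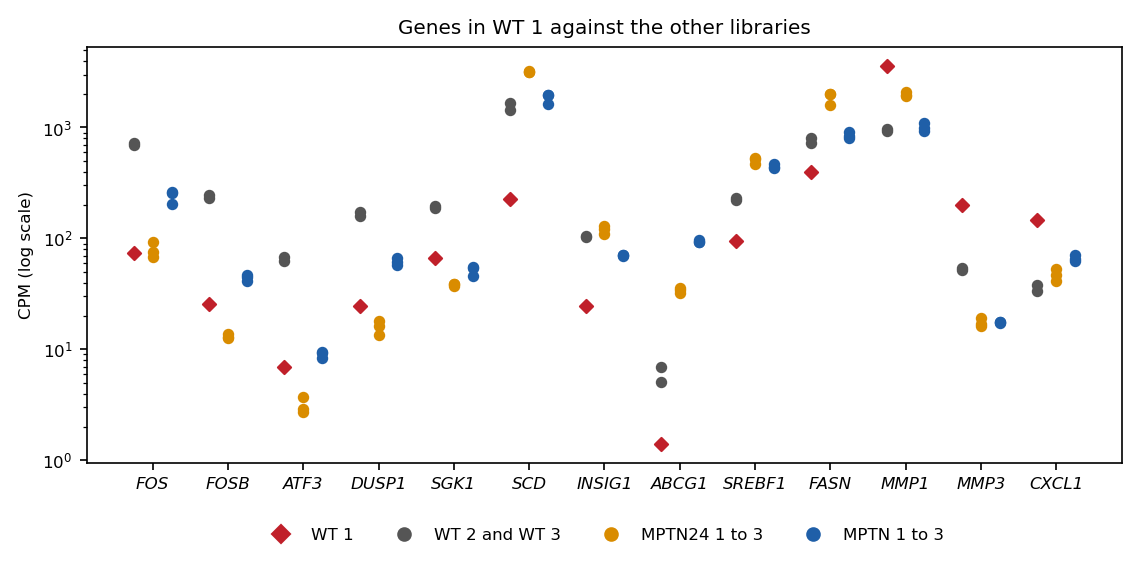
CPM of 13 transcripts in each of the 9 libraries, with WT 1 as red diamonds. FOS was at 73.4 CPM in WT 1 and MMP1 at 3590 CPM.

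The comparison of MPTN24 with WT asks which transcripts differ after 24 h with the drug. The largest changes are taken from genes at 5 CPM or more in the higher group, and positions are on GRCh38. ABCG1 (ENSG00000160179, chromosome 21, 42199689 to 42297244), which encodes an exporter of cholesterol, was 7.52-fold higher in MPTN24 (34 ± 1.6 CPM) than in WT (4.49 ± 2.8 CPM, mean ± SD, n = 3; log2 change 2.91 ± 0.48, edgeR adjusted p = 0.0067, from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The neurotensin receptor gene NTSR1 (ENSG00000101188, chromosome 20, 62708836 to 62762771) rose 5.64-fold, to 5.58 ± 0.74 CPM (log2 change 2.5 ± 0.23, edgeR adjusted p = 4.6e-05), and NOXA1 (ENSG00000188747, chromosome 9, 137423350 to 137434406), an activator of NADPH oxidase 1, rose 4.3-fold (8.07 ± 1.6 CPM against 1.86 ± 0.9 CPM, log2 change 2.11 ± 0.28, edgeR adjusted p = 0.00038). Other large rises were in ANPEP (ENSG00000166825, chromosome 15, 89784895 to 89815401), a membrane aminopeptidase (4.06-fold, log2 change 2.02 ± 0.19, edgeR adjusted p = 4.1e-05), ADM2 (ENSG00000128165, chromosome 22, 50481543 to 50486440), a peptide hormone of the calcitonin family (3.43-fold, log2 change 1.78 ± 0.19, edgeR adjusted p = 9.7e-05), and ADAM19 (ENSG00000135074, chromosome 5, 157395534 to 157575775), a membrane metalloprotease (3.43-fold, log2 change 1.78 ± 0.19, edgeR adjusted p = 9.7e-05). In total 1884 genes rose and 2052 fell, 23.2% of those tested, and 378 and 143 of them had an estimated change of 2-fold or more. Protein-coding genes made up 1718 of the rises and 1963 of the falls, and long noncoding RNAs 125 and 69.

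The largest falls at this level of expression included stress-inducible transcripts. The stress-response transcription factor gene ATF3 (ENSG00000162772, chromosome 1, 212565334 to 212620777) fell from 45.7 ± 34 CPM in WT to 3.14 ± 0.54 CPM in MPTN24 (log2 change -3.86 ± 0.83, edgeR adjusted p = 0.02), and FOSB (ENSG00000125740, chromosome 19, 45467995 to 45475179), a partner of JUN in AP-1, fell from 167 ± 120 CPM to 13.1 ± 0.6 CPM (log2 change -3.67 ± 0.81, edgeR adjusted p = 0.023). DUSP1 (ENSG00000120129, chromosome 5, 172768096 to 172771195) fell from 119 ± 82 CPM to 15.9 ± 2.2 CPM (log2 change -2.9 ± 0.69, edgeR adjusted p = 0.029), and the stromelysin gene MMP3 (ENSG00000149968, chromosome 11, 102835801 to 102843609) from 102 ± 85 CPM to 17.5 ± 1.4 CPM (log2 change -2.55 ± 0.56, edgeR adjusted p = 0.022). ALPP (ENSG00000163283, chromosome 2, 232378724 to 232382889), which encodes placental alkaline phosphatase, fell from 8.56 ± 4.2 CPM to 1.51 ± 0.54 CPM (log2 change -2.51 ± 0.38, edgeR adjusted p = 0.00095), and the inflammatory cytokine gene IL6 (ENSG00000136244, chromosome 7, 22725884 to 22732002) from 9.48 ± 4 CPM to 1.7 ± 0.42 CPM (log2 change -2.48 ± 0.3, edgeR adjusted p = 0.00021). In WT 1 alone ATF3 was at 7 CPM and FOSB at 25.4 CPM, against 67.9 and 62.1 CPM and 245 and 231 CPM in the other WT libraries. The call for ATF3 was lost without WT 2 (0.06), WT 3 (0.051), MPTN24 1 (0.086), MPTN24 2 (0.06) or MPTN24 3 (0.081), that for FOSB without WT 2 (0.067), WT 3 (0.057), MPTN24 1 (0.092), MPTN24 2 (0.073) or MPTN24 3 (0.084), and that for DUSP1 without WT 2 (0.085), WT 3 (0.073), MPTN24 1 (0.1), MPTN24 2 (0.078), MPTN24 3 (0.1), MPTN 1 (0.054) or MPTN 2 (0.055), each as adjusted p. MMP3 lost its call without MPTN24 1 (0.086), MPTN24 2 (0.074) or MPTN24 3 (0.073). The 4 calls were also lost with a replicate block (0.055, 0.067, 0.081 and 0.052) and when only the 2 groups were fitted (0.066, 0.072, 0.084 and 0.07). With limma on log2 of FPKM plus 0.1 or 1, ATF3 (-3.18 and -2.68, adjusted p = 0.064 and 0.077), FOSB (-2.99 and -2.74, 0.073 and 0.079) and DUSP1 (-2.4 and -2.29, 0.094 and 0.095) had no call. At a pseudocount of 1 the log2 changes of other genes were drawn toward 0, to 0.88 for NTSR1, 1.44 for NOXA1, 1.28 for ANPEP, 0.8 for ADM2, 0.81 for ADAM19, -1.19 for ALPP and -1.81 for IL6. Without WT 1 MMP3 was at -1.6. The counts of changed genes depended on single libraries: 1022 rose without MPTN24 1 and 1090 without MPTN24 3, while 1172 fell without WT 2, 935 without MPTN24 1 and 1097 without MPTN24 3. Without WT 1, 2286 rose and 2535 fell. Rises were 47.9% of the calls, against 59.3% with upper-quartile normalization and 65.8% and 65% with limma on log2 of FPKM plus 0.1 or 1, where 909 and 902 genes fell.

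Genes of the cell cycle fell within 24 h. After each list's counts, brackets give rises and falls adjusted over the list alone. The median log2 change follows where the list passed, then the adjusted p of camera. After the word estimated comes that with the correlation estimated for the list. Of the DNA replication genes, 0 rose, 19 fell and 11 did not pass (0 and 20, median log2 -0.34, camera adjusted p = 1.3e-09, estimated 0.045). Falls numbered 12 without MPTN24 3. The cyclin gene CCNE2 (ENSG00000175305, chromosome 8, 94879770 to 94896678) fell to 5.94 ± 0.68 CPM from 13.5 ± 2.5 CPM (log2 change -1.19 ± 0.16, edgeR adjusted p = 0.00042), and the replication factors MCM10 (-0.83 ± 0.12), CLSPN (-0.71 ± 0.14) and RFC3 (-0.71 ± 0.12, log2 change ± SE) fell as well. Of the mitosis genes, 0 rose, 18 fell and 12 did not pass (0 and 19, median log2 -0.32, camera adjusted p = 7.5e-06, estimated 0.15). Falls numbered 9 without WT 2 or with GC offsets, 7 without MPTN24 1, 8 without MPTN24 2 and 10 without MPTN24 3. The kinesins KIF11 (-0.63 ± 0.12) and KIF23 (-0.62 ± 0.11), the centromere-bound motor CENPE (-0.74 ± 0.22) and CENPF, a kinetochore protein (-0.66 ± 0.16), fell. CENPE lost its call without WT 2 (0.13), MPTN24 1 (0.13), MPTN24 2 (0.12), MPTN 2 (0.052) or MPTN 3 (0.051), with GC content and length offsets (0.11), a replicate block (0.1), only the 2 groups (0.067) and limma on log2 of FPKM plus 0.1 (0.098) or 1 (0.094). CENPF lost it without WT 2 (0.054) or MPTN24 1 (0.065), and with limma (0.058 and 0.056). Of the heat shock proteins, 0 rose, 11 fell and 10 did not pass (0 and 11, median log2 -0.4, camera adjusted p = 1.2e-05, estimated 0.23). They included CHORDC1, a co-chaperone (-0.88 ± 0.13), HSP90AA1, the inducible cytosolic HSP90, which fell from 2330 ± 130 CPM to 1410 ± 82 CPM (-0.73 ± 0.1), HSPA4L (-0.72 ± 0.14; adjusted p = 0.052 with limma on log2 of FPKM plus 0.1) and the mitochondrial co-chaperonin HSPE1 (-0.71 ± 0.12).

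Interferon-stimulated genes were already higher at 24 h: 13 rose, 1 fell and 26 did not pass (16 and 1, median log2 0.38, camera adjusted p = 3.4e-05, estimated 0.045). Rises numbered 8 without MPTN24 3. OASL (ENSG00000135114, chromosome 12, 121019111 to 121039242), an antiviral protein related to oligoadenylate synthetases, rose 3.09-fold (4.1 ± 0.79 CPM against 1.33 ± 0.1 CPM, log2 change 1.63 ± 0.15, edgeR adjusted p = 5e-05). IRF9 (1.22 ± 0.24) and STAT2 (0.87 ± 0.1), subunits of an interferon-activated transcription factor, also rose. IFI44L (ENSG00000137959, chromosome 1, 78619922 to 78646145), near the detection floor, was at 0.57 ± 0.37 CPM against 0.173 ± 0.083 CPM (log2 change 1.68 ± 0.44, edgeR adjusted p = 0.018); its call was lost without WT 2 (0.059) or MPTN24 3 (0.084), with only the 2 groups (0.11) and with limma on log2 of FPKM plus 0.1 (0.64, 0.23) or 1 (0.11, 0.55), and without MPTN24 3 its log2 change was 1.04. OASL was at 0.72 with limma plus 1. YAP and TEAD targets fell: 2 rose, 12 fell and 9 did not pass (2 and 14, median log2 -0.46, camera adjusted p = 5.3e-05, estimated 0.23). The insulin-like growth factor carrier IGFBP3 (-1.17 ± 0.14) and the tissue factor gene F3 (-0.82 ± 0.1, 1060 ± 78 CPM against 1860 ± 65 CPM) fell. The muscle ankyrin repeat gene ANKRD1 (-1.55 ± 0.43) fell, but the call was lost without WT 3 (0.091), MPTN24 1 (0.082) or MPTN24 3 (0.084) and with limma plus 1 (-0.46, 0.062). TGFB2 (ENSG00000092969, chromosome 1, 218345336 to 218444619), a transforming growth factor, fell (-1.23 ± 0.32), a call lost without WT 2 (0.072), WT 3 (0.052) or MPTN24 2 (0.055) and with limma plus 0.1 (-0.95, 0.088) or 1 (-0.47, 0.068). GADD45B, a stress-response gene, rose (0.48 ± 0.15) and lost its call without WT 2 (0.14), WT 3 (0.097), MPTN24 1 (0.064), MPTN24 2 (0.099), MPTN24 3 (0.097) or MPTN 2 (0.053), with GC offsets (0.22) and with only the 2 groups (0.059).

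Of the fatty acid synthesis genes at 24 h, 7 rose, 0 fell and 8 did not pass (7 and 0, median log2 0.45, camera adjusted p = 6.2e-05, estimated 0.29). FASN (ENSG00000169710, chromosome 17, 82078338 to 82098294), fatty acid synthase, rose from 640 ± 220 CPM to 1860 ± 240 CPM (log2 change 1.54 ± 0.22, edgeR adjusted p = 0.0011), and SREBF1 (ENSG00000072310, chromosome 17, 17810399 to 17837011), the lipogenic transcription factor, from 182 ± 76 CPM to 505 ± 34 CPM (log2 change 1.47 ± 0.29, edgeR adjusted p = 0.0091). The acetyl-CoA synthetase ACSS2 (1.46 ± 0.2) and the mitochondrial carboxylase ACACB (0.98 ± 0.23; 0.63 and 0.17 with limma on log2 of FPKM plus 0.1 or 1, adjusted p = 0.24 and 0.25) rose. For cholesterol synthesis, 8 rose, 1 fell and 18 did not pass (9 and 1, median log2 0.26, camera adjusted p = 0.00021, estimated 0.64). Rises numbered 5 with GC offsets. Here and below, further list members are those with the largest change in their list, chosen after the values were seen. TM7SF2 (1.28 ± 0.27), LSS (1.09 ± 0.16) and MVD (0.92 ± 0.16), enzymes of sterol synthesis, rose, and TMEM97 (-0.48 ± 0.09) fell. Without WT 1, 10 rose and 6 fell (camera adjusted p = 0.033). The call was lost with fry (0.12). Of the lysosome genes, 12 rose, 1 fell and 22 did not pass (15 and 2, median log2 0.25, camera adjusted p = 0.0024, estimated 0.29). Rises numbered 5 without WT 2, 6 without WT 3, 2 without MPTN24 1, 3 without MPTN24 3 and 7 without MPTN 2. GAA (0.59 ± 0.12), NEU1 (0.52 ± 0.12) and GLB1 (0.46 ± 0.09), lysosomal hydrolases, rose. Among ABC transporters, 6 rose, 3 fell and 8 did not pass (7 and 4, median log2 0.38, camera adjusted p = 0.018, estimated 0.29). ABCG1, ABCA1 (1.47 ± 0.25) and ABCC3 rose, while the drug exporters ABCC4 (-0.5 ± 0.12) and ABCG2 fell. The list's call was lost without WT 3 (0.061).

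At 24 h the ATF4 stress response gave 15 rises, 4 falls and 14 that did not pass (15 and 4, median log2 0.41, camera adjusted p = 0.00035, estimated 0.58). CHAC1 (1.32 ± 0.13), SLC1A4 (1.32 ± 0.2) and PCK2 (1.19 ± 0.22), which act in glutathione breakdown, amino acid uptake and gluconeogenesis, rose, while ATF3 and PPP1R15A (-0.9 ± 0.11), which ends the stress response, fell. This call was lost without WT 1 (0.1) and with fry (0.066). Of NRF2 antioxidant genes, 2 rose, 9 fell and 20 did not pass (2 and 9, median log2 -0.18, camera adjusted p = 0.028, estimated 0.58). NFE2L2 (-0.85 ± 0.16), the transcription factor itself, SLC7A11 (-0.77 ± 0.17) and GCLM (-0.73 ± 0.13) fell, and ABCC3 (0.7 ± 0.1), an exporter of conjugates, rose. The call was lost without WT 3 (0.15), without MPTN24 2 (0.085), with counts divided by 4 (0.053) and with fry (0.055). Falls numbered 5 without MPTN24 1. Antigen presentation gave 8 rises, 0 falls and 12 that did not pass (9 and 1, median log2 0.25, camera adjusted p = 0.021, estimated 0.7), with rises in HLA-G (0.67 ± 0.22) and HLA-B (0.45 ± 0.12), and its call was lost without WT 2 (0.12), without WT 3 (0.15), with GC offsets (0.066) and with fry (0.1). Rises numbered 5 without MPTN24 2 or MPTN 2 or with no filter, 2 without WT 2 or MPTN24 1, 1 without WT 3 or MPTN24 3 and 0 with GC offsets. Nuclear genes of the mitochondrial respiratory chain gave 0 rises, 5 falls and 35 that did not pass (0 and 2, median log2 -0.14, camera adjusted p = 0.028, estimated 0.85). NDUFA5 (-0.49 ± 0.13) fell. The call was lost without WT 3 (0.12), MPTN24 2 (0.12) or MPTN24 3 (0.068), with GC offsets (0.12) and with fry (0.24). Falls numbered 8 without WT 1, 0 without WT 2, MPTN24 1 or MPTN24 2, 3 without WT 3, 1 without MPTN24 3 and 2 without MPTN 2. Mitochondrial genome transcripts, a sign of RNA quality, gave 6 rises, 1 fall and 6 that did not pass (7 and 1, median log2 0.61, camera adjusted p = 0.0027, estimated 0.64). MT-CO1 (1.2 ± 0.3) rose and MT-ND3 (-0.55 ± 0.15) fell. Rises numbered 3 without WT 2 or MPTN 3 or with no filter, 11 without WT 1, 1 without WT 3 or MPTN24 1 and 2 without MPTN24 3. The call was lost with fry (0.13). Leukocyte markers gave 6 rises, 0 falls and 1 that did not pass (6 and 0, median log2 0.65, camera adjusted p = 0.00019, estimated 0.15). Rises numbered 3 without WT 3 and 2 without MPTN24 1 or MPTN24 3 or with GC offsets. ITGAM (1.62 ± 0.5), LAPTM5 (1.49 ± 0.16) and CD14 (0.76 ± 0.2) rose, but these encode an integrin, a lysosomal protein and a lipopolysaccharide receptor, and the pan-leukocyte gene PTPRC had 0 counts.

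The remaining lists did not pass at 24 h. For VEGF receptors, ligands and other apatinib target kinases, 2 rose, 1 fell and 9 did not pass (3 and 1, camera adjusted p = 0.23). PGF (1.08 ± 0.25) and VEGFA rose, and VEGFC (-0.56 ± 0.12) fell. For other receptor kinases and ligands, 4 rose, 4 fell and 21 did not pass (4 and 4, camera adjusted p = 0.88), with ERBB2 (0.58 ± 0.09) among the rises and NRG1 (-1.36 ± 0.13) among the falls. MAPK pathway output genes were split, since 2 rose, 3 fell and 16 did not pass (2 and 3, camera adjusted p = 0.87), with SPRY4 (1.02 ± 0.21) and MYC (-0.7 ± 0.11) in opposite directions. Among mesenchymal markers, 6 rose, 3 fell and 16 did not pass (6 and 3, camera adjusted p = 0.33). COL6A1 (1.18 ± 0.12) rose and THBS1 (-1.56 ± 0.16) fell. Among epithelial junction genes, 6 rose, 6 fell and 16 did not pass (6 and 7, camera adjusted p = 0.53), and TJP3 (2 ± 0.35) and CLDN4 (1.46 ± 0.11) rose. Among keratinocyte differentiation genes, 3 rose, 0 fell and 19 did not pass (3 and 0, camera adjusted p = 0.26), with EVPL (0.6 ± 0.15) the largest. Of basal keratinocyte genes, 4 rose, 4 fell and 9 did not pass (4 and 5, camera adjusted p = 0.88). ITGA3 (0.8 ± 0.11) rose and TP63 (-0.62 ± 0.13) fell. Autophagy genes gave 6 rises, 1 fall and 22 that did not pass (6 and 1, camera adjusted p = 0.31), with WIPI1 (0.7 ± 0.12) among the rises. Endoplasmic reticulum chaperones gave 1 rise, 0 falls and 20 that did not pass (1 and 0, camera adjusted p = 0.68). The rise was XBP1 (0.39 ± 0.1).

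Ferroptosis and iron genes at 24 h gave 4 rises, 5 falls and 13 that did not pass (5 and 6, camera adjusted p = 0.74). ALOX5 (0.88 ± 0.25) was higher and PTGS2 (-1.79 ± 0.19) lower. In the hypoxia response, 8 rose, 5 fell and 19 did not pass (10 and 6, camera adjusted p = 0.6). ALDOC (1.06 ± 0.18) rose while ADM (-1.32 ± 0.1) fell. NF-kB cytokines gave 2 rises, 7 falls and 26 that did not pass (3 and 8, camera adjusted p = 0.58). CCL5 (1.83 ± 0.32) and IL1RN (1.44 ± 0.15) rose, and IL6 and PTGS2 fell. The list turned to Up without WT 1, where 15 rose and 6 fell (0.11). Xenobiotic metabolism gave 3 rises, 2 falls and 21 that did not pass (3 and 2, camera adjusted p = 0.49). ALDH3B1 (1.22 ± 0.16) was higher and AHR (-0.58 ± 0.15) lower. Stem cell markers gave 3 rises, 3 falls and 8 that did not pass (3 and 4, camera adjusted p = 0.88). NES (0.71 ± 0.23) was higher and EZH2 (-0.53 ± 0.1) lower. Of p53 targets, 7 rose, 3 fell and 16 did not pass (7 and 4, camera adjusted p = 0.33). GDF15 (1.61 ± 0.28) and BBC3 (0.83 ± 0.17) rose. BCL2 and IAP families gave 3 rises, 3 falls and 14 that did not pass (3 and 3, camera adjusted p = 0.88). BMF (0.96 ± 0.17) was higher and BCL2L11 (-0.66 ± 0.19) lower, both of them promoters of cell death.

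Matrix proteases at 24 h gave 8 rises, 4 falls and 15 that did not pass (10 and 6, camera adjusted p = 0.46). ADAMTS1 (-2.12 ± 0.14) and MMP13 (-1.96 ± 0.27) were lower, and the list passed without WT 1 (0.033; 13 rose, 5 fell). WNT targets gave 1 rise, 1 fall and 8 that did not pass (1 and 1, camera adjusted p = 0.87), with TCF7 (0.74 ± 0.13) and DKK1 (-0.6 ± 0.09) in opposite directions. TGF-beta targets gave 3 rises, 5 falls and 14 that did not pass (4 and 8, camera adjusted p = 0.68). ID2 (-2.75 ± 0.81) and INHBA (-1.09 ± 0.15) were lower and LTBP3 (0.92 ± 0.14) higher. Cytosolic ribosomal proteins gave 0 rises, 2 falls and 57 that did not pass (0 and 0, camera adjusted p = 0.69). RPS29 (-0.72 ± 0.22) was lower. Replication-dependent histones gave 0 rises, 0 falls and 29 that did not pass (0 and 0, camera adjusted p = 0.69). Fibroblast markers gave 1 rise, 0 falls and 8 that did not pass (1 and 0, camera adjusted p = 0.77). The rise was ACTA2 (0.73 ± 0.13). Endothelial markers gave 0 rises, 0 falls and 7 that did not pass (0 and 0, camera adjusted p = 0.94). Median and mean log2 change differed in sign for epithelial junctions (-0.02 and 0.1), basal keratinocyte (-0.14 and 0.03), MAPK output (0.12 and -0.07), matrix proteases (0.19 and -0.02), xenobiotic metabolism (0.15 and -0.09) and WNT targets (-0.11 and 0.1). The camera direction was Up for all of these but WNT targets, Up for fibroblast markers (-0.01 and -0.21) and Down for stem cell markers (0.02 and 0.47). Of the 15 list calls in this comparison, only DNA replication and interferon-stimulated genes passed with an estimated correlation.

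The comparison of MPTN with WT asks which transcripts differ in the resistant line. CXCL10 (ENSG00000169245, chromosome 4, 76021118 to 76023497), a chemokine that attracts T cells, was at 18.6 ± 1.5 CPM in MPTN and 0.0241 ± 0.042 CPM in WT, a ratio of 1070 (counting interval 192 to 42300) in read pairs, with the 5 WT counts as 1 pair (log2 change 9.57 ± 0.47, edgeR adjusted p = 1.5e-08). CCL5 (ENSG00000271503, chromosome 17, 35871491 to 35880793), another such chemokine, rose 209-fold to 63.2 ± 3.9 CPM (log2 change 7.71 ± 0.3, edgeR adjusted p = 1.1e-08), and CXCL11 (ENSG00000169248, chromosome 4, 76033682 to 76041415) rose 92.3-fold to 6.23 ± 0.85 CPM (log2 change 6.53 ± 0.55, edgeR adjusted p = 1.8e-06). IFI44L rose 96.8-fold to 17.4 ± 0.38 CPM (log2 change 6.6 ± 0.43, edgeR adjusted p = 6e-07), OASL 91.7-fold to 122 ± 11 CPM (log2 change 6.52 ± 0.17, edgeR adjusted p = 2.2e-11), and CUX2 (ENSG00000111249, chromosome 12, 111034165 to 111350554), a homeobox transcription factor of neurons, 45.7-fold to 7.44 ± 2.1 CPM (log2 change 5.51 ± 0.71, edgeR adjusted p = 0.00023). RSAD2 (ENSG00000134321, chromosome 2, 6865806 to 6898239), which encodes the antiviral enzyme viperin, was at 4.42 ± 0.41 CPM in MPTN and at 0 in WT, at least 83.6-fold higher (log2 change 11.34 ± 0.88, edgeR adjusted p = 3.1e-06). Intervals and floors of this kind cover counting error only. The interferon genes IFNB1 and IFNL1 were detected almost only in MPTN. IFNB1 (ENSG00000171855, chromosome 9, 21077104 to 21077942) had 132, 175 and 393 counts in the MPTN libraries against 5 in all of WT (159-fold in read pairs, 28.2 to 6320, with 5 counts as 1 pair), and IFNL1 (ENSG00000182393, chromosome 19, 39296407 to 39298673) had 241, 399 and 490 against 0 (at least 85.6-fold higher). IFNG had 0 counts in all 9 libraries. The log2 change of CXCL10 was 13.42 without WT 2 and 8.88 without WT 3, and without WT 3 CXCL11 was at 5.86 and CUX2 at 6.57. With limma on log2 of FPKM plus 0.1 or 1 these changes were smaller: CXCL10 7.03 and 3.96, IFI44L 4.71 and 2.08, CXCL11 4.9 and 2.25, CUX2 3.26 and 1.01, RSAD2 3.8 and 1.2, and at 1 also CCL5 5.37 and OASL 4.92. RSAD2 was at 9.35 with counts divided by 4. In total 3116 genes rose and 3071 fell, 36.4% of those tested, of which 1040 and 409 had an estimated change of 2-fold or more. Protein-coding genes made up 2740 of the rises and 2956 of the falls, and long noncoding RNAs 288 and 74.

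**Figure D2:**
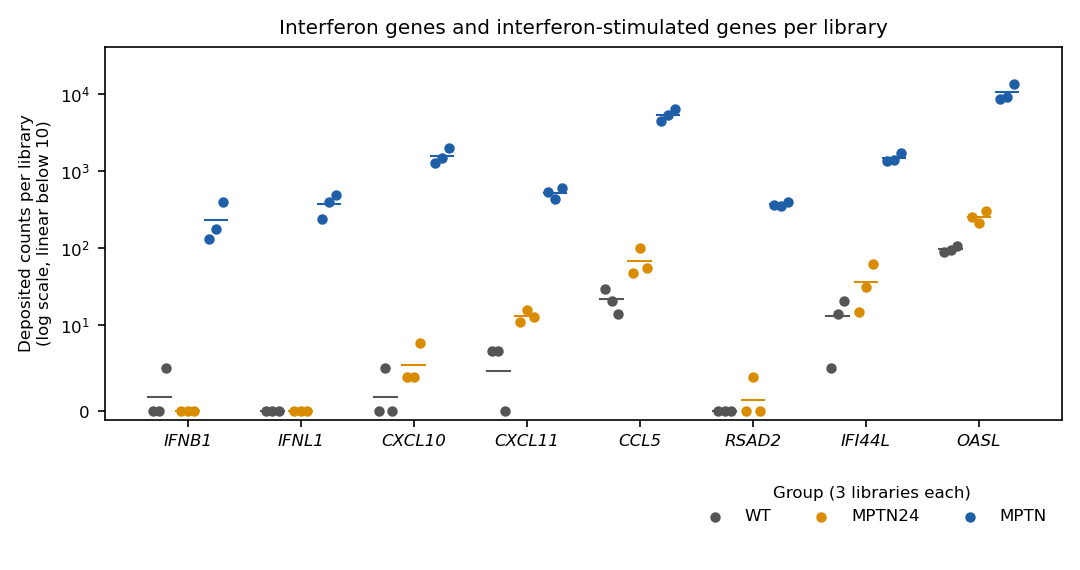
Deposited counts of IFNB1, IFNL1 and 6 interferon-stimulated genes in each library, with lines at group means. IFNB1 had 132 to 393 counts in MPTN libraries and IFNL1 241 to 490.

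Falls in MPTN against WT were smaller. MMP3 fell to 17.6 ± 0.2 CPM (log2 change -2.54 ± 0.56, edgeR adjusted p = 0.013), a call lost without MPTN 1 (0.05), MPTN 2 (0.051) or MPTN 3 (0.052), and ALPP fell to 1.71 ± 0.27 CPM (log2 change -2.32 ± 0.38, edgeR adjusted p = 0.00042). THBS1 (ENSG00000137801, chromosome 15, 39581079 to 39599466), a matrix glycoprotein that blocks angiogenesis, fell from 1580 ± 240 CPM to 349 ± 73 CPM (log2 change -2.18 ± 0.16, edgeR adjusted p = 6e-07). TGFB2 fell to 1.58 ± 0.11 CPM (log2 change -2.09 ± 0.33, edgeR adjusted p = 0.00024), the actin-binding signalling protein gene HCLS1 (ENSG00000180353, chromosome 3, 121631399 to 121660927) from 29.2 ± 0.47 CPM to 7.19 ± 0.73 CPM (log2 change -2.02 ± 0.11, edgeR adjusted p = 3.7e-08), and ALDH1A3 (ENSG00000184254, chromosome 15, 100877714 to 100916626), a retinoic acid synthesising enzyme, from 73.5 ± 10 CPM to 18.2 ± 2.6 CPM (log2 change -2.02 ± 0.15, edgeR adjusted p = 6.1e-07). Without WT 1 MMP3 was at -1.59, and 3251 genes rose and 3307 fell. Rises were 50.4% of calls, against 66.4% and 66.2% with limma on log2 of FPKM plus 0.1 or 1, where 1782 and 1778 genes fell and, at 0.1, the median log2 change of the tested genes was 0.12. ALPP was at -1.71 and -1.1 there, and at 1 TGFB2 at -0.66 and VLDLR at 1.23.

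Lists are given as before. Nearly all interferon-stimulated genes rose in MPTN: 37 rose, 0 fell and 3 did not pass (40 and 0, median log2 2.12, camera adjusted p = 5.9e-86, estimated 3e-05). Antigen presentation genes rose with them, since 14 rose, 0 fell and 6 did not pass (14 and 1, median log2 0.55, camera adjusted p = 2.2e-08, estimated 0.27). The class I genes HLA-B (ENSG00000234745, chromosome 6, 31269491 to 31357188) at 841 ± 31 CPM against 272 ± 58 CPM (1.63 ± 0.13), HLA-F (1.48 ± 0.1) and HLA-C (1.23 ± 0.1) all rose. Cell-cycle genes fell further than at 24 h. Mitosis genes gave 0 rises, 26 falls and 4 that did not pass (0 and 27, median log2 -0.84, camera adjusted p = 7.6e-23, estimated 0.0077), and DNA replication genes gave 0 rises, 27 falls and 3 that did not pass (0 and 27, median log2 -0.73, camera adjusted p = 3e-21, estimated 0.0045). MKI67 (ENSG00000148773, chromosome 10, 128096659 to 128126423), a marker of cycling cells, fell from 314 ± 79 CPM to 103 ± 24 CPM (log2 change -1.6 ± 0.2, edgeR adjusted p = 0.00014), KIF11 from 119 ± 14 CPM to 42.3 ± 2 CPM (-1.49 ± 0.12), and CENPF (-1.32 ± 0.16) and KIF23 (-1.24 ± 0.11) fell too. Replication genes that fell were MCM10 (-1.63 ± 0.12), CLSPN (-1.31 ± 0.14), RRM2, a subunit of ribonucleotide reductase (-1.38 ± 0.12), and UHRF1, which maintains DNA methylation (-1.18 ± 0.13).

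The ATF4 stress response in MPTN gave 21 rises, 0 falls and 12 that did not pass (22 and 1, median log2 0.54, camera adjusted p = 1.9e-08, estimated 0.27). VLDLR (ENSG00000147852, chromosome 9, 2621787 to 2660056), a lipoprotein receptor, rose 6.37-fold to 12.1 ± 1.6 CPM (log2 change 2.67 ± 0.21, edgeR adjusted p = 9.9e-07), and CHAC1, which degrades glutathione (2.18 ± 0.13), SLC1A4, a neutral amino acid transporter (2.1 ± 0.2), and TRIB3, a pseudokinase induced by stress (1.81 ± 0.23), rose with it. Lysosome genes gave 21 rises, 2 falls and 12 that did not pass (25 and 3, median log2 0.44, camera adjusted p = 2.5e-06, estimated 0.099). GAA, the glycogen-degrading glucosidase (1.21 ± 0.12), CTSB (1 ± 0.11) and CTSD (0.92 ± 0.11), both cathepsins, and GPNMB, a membrane glycoprotein of lysosomes (0.85 ± 0.14), rose. GLA, alpha-galactosidase, fell (-0.52 ± 0.12), a call lost with limma on log2 of FPKM (0.089 plus 0.1, 0.09 plus 1). Autophagy genes gave 14 rises, 0 falls and 15 that did not pass (14 and 1, median log2 0.31, camera adjusted p = 0.0007, estimated 0.044), with rises in WIPI1 (1.3 ± 0.12), BNIP3 (1.2 ± 0.13) and ULK1 (1.05 ± 0.1). Hypoxia response genes gave 18 rises, 2 falls and 12 that did not pass (18 and 2, median log2 0.55, camera adjusted p = 7.7e-06, estimated 0.029). SLC2A3 (2.14 ± 0.23), a glucose transporter, CA9 (1.78 ± 0.2), a carbonic anhydrase, and LOX (1.69 ± 0.19), which crosslinks collagen, rose. NF-kB cytokines gave 15 rises, 6 falls and 14 that did not pass (15 and 6, median log2 0.39, camera adjusted p = 7.4e-05, estimated 0.35). Rises numbered 23 without WT 1. CFB (3.56 ± 0.17) and LCN2 (2.66 ± 0.21) were higher, encoding complement factor B and lipocalin 2, while CXCL6 (-2.99 ± 0.89) and IL6 (-1.04 ± 0.28) fell. Of p53 targets, 9 rose, 2 fell and 15 did not pass (9 and 2, median log2 0.26, camera adjusted p = 0.0093, estimated 0.17). SPATA18 (3.79 ± 0.86), GDF15 (3.06 ± 0.28) and BBC3 (1.78 ± 0.17) rose and TIGAR (-0.49 ± 0.12) fell.

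Genes of ferroptosis and iron in MPTN gave 9 rises, 4 falls and 9 that did not pass (9 and 4, median log2 0.25, camera adjusted p = 0.043, estimated 0.17). ALOX5 (2.59 ± 0.25), a lipoxygenase, and the ferritin chains FTH1 (0.94 ± 0.1) and FTL (0.75 ± 0.12) rose, and TFRC (-0.64 ± 0.12), the transferrin receptor, fell. The call was lost without WT 1 (0.14) or WT 3 (0.063), with a replicate block (0.068) and with counts divided by 4 (0.055). YAP and TEAD targets gave 1 rise, 15 falls and 7 that did not pass (2 and 15, median log2 -0.48, camera adjusted p = 9.1e-05, estimated 0.17). TGFB2 and CCN1 (-0.9 ± 0.09) were lower. Heat shock proteins gave 2 rises, 12 falls and 7 that did not pass (4 and 13, median log2 -0.4, camera adjusted p = 0.00089, estimated 0.27), where HSP90AA1 (-1.06 ± 0.1) and HSPD1 (-0.96 ± 0.11) fell and the small heat shock protein HSPB8 (2.03 ± 0.29) rose. Of 13 list calls, interferon-stimulated genes, hypoxia response, autophagy, mitosis and DNA replication passed with an estimated correlation.

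Other lists did not pass in MPTN against WT. For cholesterol synthesis, 2 rose, 7 fell and 18 did not pass (1 and 5, camera adjusted p = 0.27), with TMEM97 (-1.15 ± 0.1) and HMGCS1 (-1.15 ± 0.33) among the falls. Without WT 1 the list passed downward (2 rose, 14 fell, 4.2e-06). For fatty acid synthesis, 4 rose, 4 fell and 7 did not pass (4 and 4, camera adjusted p = 0.74). SREBF1 (1.29 ± 0.29) rose and ACLY (-0.63 ± 0.14) fell. For ABC transporters, 8 rose, 5 fell and 4 did not pass (9 and 5, camera adjusted p = 0.065). ABCG1 (4.39 ± 0.5) and ABCA1 (2.11 ± 0.25) were higher and ABCC2 (-1.02 ± 0.22) lower. The list passed without WT 1 (0.0024), WT 2 (0.0086) or MPTN 3 (0.045) and with no filter (0.031). For the respiratory chain, 1 rose, 12 fell and 27 did not pass (1 and 12, camera adjusted p = 0.053). COX6C (-0.68 ± 0.11) and ATP5F1A (-0.67 ± 0.09) fell. The list passed without WT 1 (0.018), WT 2 (0.048) or MPTN 3 (0.00064), with RLE factors (0.047), with no filter (0.0052) and with GC offsets (0.04). For cytosolic ribosomal proteins, 0 rose, 8 fell and 51 did not pass (0 and 5, camera adjusted p = 0.089). RPL7 (-0.64 ± 0.09) was lower. The list passed without WT 1 (0.033) or MPTN 3 (7.6e-05), with GC offsets (0.015) and with no filter (0.0098). For mitochondrial genome transcripts, 3 rose, 1 fell and 9 did not pass (3 and 1, camera adjusted p = 0.27), and they passed upward without WT 1 (4.8e-09). For mesenchymal markers, 7 rose, 4 fell and 14 did not pass (7 and 4, camera adjusted p = 0.095). COL6A2 (3.01 ± 0.13) was higher and FN1 (-1.46 ± 0.2) lower, and the list passed without MPTN 3 (0.045).

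Growth factor and receptor lists of MPTN were mixed. The VEGF and apatinib target list gave 3 rises, 0 falls and 9 that did not pass (3 and 0, camera adjusted p = 0.27), the rises being VEGFA, PGF (0.95 ± 0.24) and VEGFB (0.74 ± 0.13). Other receptor kinases and ligands gave 10 rises, 5 falls and 14 that did not pass (12 and 5, camera adjusted p = 0.63). BTC (2.82 ± 0.37), an EGFR ligand, FGFR1 (1.97 ± 0.29) and FGF2 (1.19 ± 0.14) rose and NRG1 (-1.94 ± 0.14) fell. MAPK output genes gave 4 rises, 3 falls and 14 that did not pass (4 and 3, camera adjusted p = 0.95). SPRY4 (0.98 ± 0.21) was higher and MYC (-0.86 ± 0.11) lower. Epithelial junction genes gave 9 rises, 9 falls and 10 that did not pass (10 and 9, camera adjusted p = 0.94). CLDN4 (1.56 ± 0.11) rose and EPCAM (-1.01 ± 0.1) fell. Keratinocyte differentiation genes gave 1 rise, 1 fall and 20 that did not pass (0 and 0, camera adjusted p = 0.96). KRT13 (-2.62 ± 0.87) was lower. Basal keratinocyte genes gave 5 rises, 3 falls and 9 that did not pass (5 and 3, camera adjusted p = 0.27). KRT6B (2.03 ± 0.17) and KRT17 (0.67 ± 0.23) were higher. Endoplasmic reticulum chaperones in MPTN had 4 rises, 0 falls and 17 that did not pass (4 and 0, camera adjusted p = 0.72). DNAJB9 (0.82 ± 0.12) was higher. NRF2 genes gave 9 rises, 9 falls and 13 that did not pass (9 and 9, camera adjusted p = 0.96). FTH1 and HMOX1 (0.91 ± 0.18) rose and ABCC2 (-1.02 ± 0.22) fell. Xenobiotic metabolism in MPTN gave 6 rises, 4 falls and 16 that did not pass (7 and 6, camera adjusted p = 0.76). CYP1A1 (-2.84 ± 0.29) was lower and ALDH1A1 (1.04 ± 0.31) higher.

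Stem cell markers in MPTN gave 2 rises, 3 falls and 9 that did not pass (2 and 2, camera adjusted p = 0.63). ALDH1A1 was higher and EZH2 (-0.74 ± 0.1) lower. BCL2 and IAP genes gave 8 rises, 1 fall and 11 that did not pass (8 and 3, camera adjusted p = 0.13). BBC3, HRK (1.49 ± 0.53) and BCL2L1 (0.72 ± 0.09) rose. Matrix proteases in MPTN gave 10 rises, 6 falls and 11 that did not pass (10 and 7, camera adjusted p = 0.94). MMP28 (1.52 ± 0.29) was higher and ADAMTS1 (-1.41 ± 0.13) lower. WNT targets in MPTN gave 2 rises, 3 falls and 5 that did not pass (3 and 3, camera adjusted p = 0.51). BAMBI (3.05 ± 1.01) rose and DKK1 (-1.19 ± 0.09) fell. TGF-beta targets in MPTN gave 4 rises, 5 falls and 13 that did not pass (4 and 5, camera adjusted p = 0.96). LTBP3 (1 ± 0.14) was higher and INHBA (-0.74 ± 0.15) lower. Histones gave 5 rises, 0 falls and 24 that did not pass (3 and 0, camera adjusted p = 0.94). H4C12 (1.95 ± 0.65) and H2AC6 (0.87 ± 0.1) were higher. Leukocyte markers in MPTN gave 2 rises, 2 falls and 3 that did not pass (3 and 2, camera adjusted p = 0.94). CD14 (0.83 ± 0.2) rose and CORO1A (-1.15 ± 0.13) fell. Fibroblast markers in MPTN gave 0 rises, 1 fall and 8 that did not pass (0 and 1, camera adjusted p = 0.63). MFAP5 (-2 ± 0.6) was lower. Endothelial markers in MPTN gave 0 rises, 0 falls and 7 that did not pass (0 and 0, camera adjusted p = 0.96). Median and mean differed in sign for MAPK output (-0.08 and 0.11), epithelial junctions (-0.04 and 0.07), chaperones (-0.07 and 0.08), stem cell markers (-0.16 and 0.33) and endothelial markers (-0.03 and 0.13). The camera direction was Up for all of these but stem cell markers, and was opposite to both values for keratinocyte differentiation (-0.06 and -0.25, Up), matrix proteases (-0.23 and -0.27, Up), WNT targets (0.09 and 0.26, Down) and histones (-0.08 and -0.12, Up).

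The comparison of MPTN with MPTN24 asks how the resistant line differs from cells after 24 h of drug. The largest rises were again in interferon-related genes: CXCL10 rose 214-fold (log2 change 7.74 ± 0.41, edgeR adjusted p = 7.5e-08), CCL5 58.7-fold (log2 change 5.88 ± 0.27, edgeR adjusted p = 6.6e-08), IFI44L 30.3-fold (log2 change 4.92 ± 0.38, edgeR adjusted p = 6.7e-06), OASL 29.7-fold (log2 change 4.89 ± 0.15, edgeR adjusted p = 3.1e-10) and CXCL11 29.1-fold (log2 change 4.86 ± 0.49, edgeR adjusted p = 2.7e-05). CUX2 rose 22.6-fold from 0.326 ± 0.1 CPM (log2 change 4.5 ± 0.66, edgeR adjusted p = 0.0019). RSAD2 was 215-fold higher, with a counting interval of 38.2 to 8510 (log2 change 7.6 ± 0.65, edgeR adjusted p = 2.1e-05), IFNB1 at least 45.4-fold and IFNL1 at least 73.2-fold. RSAD2 was at 11.36 without MPTN24 2 and IFI44L at 5.56 without MPTN24 3. With limma on log2 of FPKM plus 0.1 or 1, CXCL10 was at 6.51 and 3.9, IFI44L at 4.07 and 1.97, CXCL11 at 4.17 and 2.14, CUX2 at 2.99 and 0.98, RSAD2 at 3.74 and 1.2, and at 1 CCL5 at 4.86, OASL at 4.21, UPK2 at -2.07, PADI3 at -2.29 and LAPTM5 at -1.55. UPK2 (ENSG00000110375, chromosome 11, 118925164 to 118958559), a urothelial membrane protein, fell from 6.54 ± 1.1 CPM to 0.75 ± 0.28 CPM (log2 change -3.11 ± 0.3, edgeR adjusted p = 2.2e-05), and AQP3 (ENSG00000165272, chromosome 9, 33441156 to 33447596), a water and glycerol channel, from 456 ± 17 CPM to 71.5 ± 5.6 CPM (log2 change -2.67 ± 0.25, edgeR adjusted p = 0.0002). ALDH1A3 (log2 change -2.25 ± 0.15, edgeR adjusted p = 4.3e-07), LAPTM5 (ENSG00000162511, chromosome 1, 30732469 to 30757774), a lysosomal protein (log2 change -2.18 ± 0.16, edgeR adjusted p = 1.5e-06), and HCLS1 (log2 change -1.97 ± 0.11, edgeR adjusted p = 1.1e-07) fell as well. PADI3 (ENSG00000142619, chromosome 1, 17249098 to 17284233), which citrullinates proteins, fell from 41.4 ± 4.4 CPM to 5.45 ± 0.77 CPM (log2 change -2.93 ± 0.69, edgeR adjusted p = 0.038). This call was lost without WT 2 (0.057), WT 3 (0.053), MPTN24 1 (0.1), MPTN24 2 (0.082), MPTN24 3 (0.097), MPTN 1 (0.12), MPTN 2 (0.14) or MPTN 3 (0.11). It was also lost with no filter (0.062), with a replicate block (0.096) and with limma on log2 of FPKM plus 0.1 (0.068).

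In total 1334 genes rose and 1138 fell in MPTN against MPTN24, 14.5% of those tested, and 368 and 134 of them had an estimated change of 2-fold or more. Protein-coding genes were 1203 of the rises and 1087 of the falls, and long noncoding RNAs 110 and 29. The rises were 777, 830 and 741 without MPTN24 1, 2 or 3, and 859 and 792 without MPTN 1 or 2. The falls were 650 and 569 without MPTN24 1 or 3, 753 and 610 without MPTN 1 or 2, and 1732 without WT 1, where 1860 rose. Rises were 54% of calls, against 68.6% and 70% with limma on log2 of FPKM plus 0.1 or 1, where 573 and 566 genes fell.

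For MPTN against MPTN24, lists are given as before. Interferon-stimulated genes gave 39 rises, 0 falls and 1 that did not pass (40 and 0, median log2 1.62, camera adjusted p = 9.7e-138, estimated 6.6e-06). Mitosis genes again fell, with 0 rises, 24 falls and 6 that did not pass (0 and 26, median log2 -0.56, camera adjusted p = 1.1e-19, estimated 0.011), as did DNA replication genes, with 0 rises, 17 falls and 13 that did not pass (0 and 22, median log2 -0.38, camera adjusted p = 8.7e-12, estimated 0.011). MKI67 fell from 209 ± 20 CPM to 103 ± 24 CPM (log2 change -1.02 ± 0.2, edgeR adjusted p = 0.0068), and KIF11 (-0.86 ± 0.12), KIF2C, a microtubule depolymerase (-0.78 ± 0.1), and AURKB, a mitotic kinase (-0.76 ± 0.13), fell. Replication genes that fell included LIG1, DNA ligase 1 (-0.81 ± 0.1), MCM10 (-0.8 ± 0.12), RRM2 (-0.75 ± 0.12) and RRM1 (-0.68 ± 0.1). NF-kB cytokines gave 14 rises, 1 fall and 20 that did not pass (16 and 4, median log2 0.5, camera adjusted p = 5.8e-13, estimated 0.13). CFB rose 8.93-fold to 183 ± 5.5 CPM (log2 change 3.16 ± 0.17, edgeR adjusted p = 7.5e-08), and LCN2 (2.13 ± 0.2) and the neutrophil attractant CXCL8 (1.53 ± 0.11) rose. IL1B, interleukin 1 beta, fell (-0.4 ± 0.12), a call lost without MPTN24 1 (0.095), MPTN24 2 (0.12), MPTN24 3 (0.11), MPTN 1 (0.089), MPTN 2 (0.12) or MPTN 3 (0.1), with upper-quartile normalization (0.0503), with GC offsets (0.052) and with limma on log2 of FPKM plus 0.1 (0.073) or 1 (0.076). Cholesterol synthesis genes gave 0 rises, 11 falls and 16 that did not pass (0 and 13, median log2 -0.65, camera adjusted p = 4.8e-10, estimated 0.35). Falls numbered 20 without WT 1, 6 without MPTN24 1 and 7 without MPTN24 3 or MPTN 1. ACAT2 (-1.23 ± 0.14), MVD (-0.92 ± 0.16), FDPS (-0.9 ± 0.11) and LSS (-0.9 ± 0.16), enzymes from acetyl-CoA to lanosterol, fell. Hypoxia response genes in MPTN against MPTN24 gave 15 rises, 0 falls and 17 that did not pass (18 and 1, median log2 0.45, camera adjusted p = 4.4e-09, estimated 0.011). EGLN3, a prolyl hydroxylase induced by HIF, rose 3.14-fold (1.65 ± 0.17), with SLC2A3 (1.29 ± 0.22), CA9 (1.2 ± 0.2) and LOX (1.08 ± 0.19).

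Fatty acid synthesis in MPTN against MPTN24 gave 0 rises, 4 falls and 11 that did not pass (0 and 6, median log2 -0.34, camera adjusted p = 0.00034, estimated 0.29). Falls numbered 9 without WT 1. FASN (-1.14 ± 0.22) and ACLY (-0.92 ± 0.14) fell. Lysosome genes had 6 rises, 0 falls and 29 that did not pass (9 and 0, median log2 0.23, camera adjusted p = 0.00056, estimated 0.17). Rises numbered 12 without WT 1 and 15 with GC offsets. CTSB (0.7 ± 0.11) was higher. Autophagy genes had 10 rises, 0 falls and 19 that did not pass (10 and 1, median log2 0.18, camera adjusted p = 0.00034, estimated 0.036). BNIP3 (1.05 ± 0.13) and GABARAPL1 (0.88 ± 0.1) were higher. The ATF4 response had 10 rises, 0 falls and 23 that did not pass (12 and 0, median log2 0.21, camera adjusted p = 1.4e-05, estimated 0.39). VLDLR (1.77 ± 0.2) and SLC7A11 (0.83 ± 0.17) rose. NRF2 genes had 9 rises, 2 falls and 20 that did not pass (12 and 4, median log2 0.13, camera adjusted p = 0.013, estimated 0.4). FTH1 (1.15 ± 0.1) and HMOX1 (0.73 ± 0.18) were higher and EPHX1 (-0.52 ± 0.15) lower. Ferroptosis and iron genes had 10 rises, 1 fall and 11 that did not pass (13 and 2, median log2 0.34, camera adjusted p = 0.00011, estimated 0.027). Rises numbered 6 without MPTN 1. ALOX5 (1.7 ± 0.24) was higher. Antigen presentation had 8 rises, 0 falls and 12 that did not pass (10 and 0, median log2 0.37, camera adjusted p = 3.4e-08, estimated 0.26). Rises numbered 5 without MPTN24 3. HLA-B (1.18 ± 0.13) and B2M (1.04 ± 0.09) were higher. The p53 targets had 8 rises, 2 falls and 16 that did not pass (10 and 2, median log2 0.2, camera adjusted p = 0.0071, estimated 0.13). GDF15 (1.46 ± 0.27) rose and TP53I3 (-0.76 ± 0.13) fell.

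BCL2 and IAP genes in MPTN against MPTN24 had 4 rises, 0 falls and 16 that did not pass (5 and 0, median log2 0.11, camera adjusted p = 0.027, estimated 0.13), with BBC3 (0.95 ± 0.17) and PMAIP1 (0.82 ± 0.11), which promote cell death, higher. The call was lost without MPTN 3 (0.074). Cytosolic ribosomal proteins had 0 rises, 4 falls and 55 that did not pass (0 and 2, median log2 -0.07, camera adjusted p = 0.046, estimated 0.83). Falls numbered 2 without MPTN24 1, MPTN24 3, MPTN 1 or MPTN 2, 9 without MPTN 3 and 13 with GC offsets. RPL3 (-0.43 ± 0.09) was lower. The list's call was lost without WT 2 (0.052), MPTN24 1 (0.3), MPTN 1 (0.48) or MPTN 2 (0.4), with counts divided by 4 (0.073) and with fry (0.48). Leukocyte markers had 1 rise, 3 falls and 3 that did not pass (1 and 3, median log2 -0.33, camera adjusted p = 0.00034, estimated 0.1). LAPTM5 and CORO1A (-1.59 ± 0.13) were lower and CD74 (0.35 ± 0.09) higher. Of these 17 list calls, interferon-stimulated genes, hypoxia response, ferroptosis and iron, autophagy, mitosis and DNA replication passed with an estimated correlation.

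Lists that did not pass in MPTN against MPTN24 began with the VEGF and apatinib target list, where 1 rose, 0 fell and 11 did not pass (1 and 0, camera adjusted p = 0.86). The rise was VEGFC (0.53 ± 0.11). Other receptor kinases and ligands had 5 rises, 4 falls and 20 that did not pass (5 and 6, camera adjusted p = 0.47). BTC (1.91 ± 0.35) and FGF2 (1.75 ± 0.14) rose. MAPK output had 1 rise, 1 fall and 19 that did not pass (1 and 1, camera adjusted p = 0.97). SPRED1 (0.69 ± 0.12) was higher. Mesenchymal markers had 5 rises, 3 falls and 17 that did not pass (6 and 5, camera adjusted p = 0.21). COL6A2 (2.15 ± 0.13) and CDH2 (1.2 ± 0.15) rose and FN1 (-1.2 ± 0.19) fell. Epithelial junctions had 4 rises, 4 falls and 20 that did not pass (6 and 6, camera adjusted p = 0.6). CLDN1 (0.99 ± 0.12) was higher and GRHL2 (-0.66 ± 0.1) lower. Keratinocyte differentiation had 1 rise, 2 falls and 19 that did not pass (1 and 2, camera adjusted p = 0.19). KRT13 (-3.59 ± 0.89) was lower. Basal keratinocyte genes had 4 rises, 0 falls and 13 that did not pass (5 and 0, camera adjusted p = 0.14). KRT17 (1.33 ± 0.23) was higher. Chaperones had 3 rises, 2 falls and 16 that did not pass (3 and 2, camera adjusted p = 0.92). DNAJB9 (0.9 ± 0.12) was higher and PDIA6 (-0.34 ± 0.1) lower. The respiratory chain had 4 rises, 7 falls and 29 that did not pass (5 and 7, camera adjusted p = 0.6). ATP5F1A (-0.49 ± 0.09) was lower and COX5B (0.49 ± 0.12) higher. The list passed without MPTN 3 (0.035).

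ABC transporters in MPTN against MPTN24 had 1 rise, 0 falls and 16 that did not pass (1 and 0, camera adjusted p = 0.75). Xenobiotic metabolism had 3 rises, 2 falls and 21 that did not pass (3 and 6, camera adjusted p = 0.11). CYP1A1 (-2.82 ± 0.29) fell. Stem cell markers had 3 rises, 2 falls and 9 that did not pass (3 and 2, camera adjusted p = 0.45). KLF4 (1.51 ± 0.31) was higher and NES (-1 ± 0.23) lower. YAP and TEAD targets had 2 rises, 5 falls and 16 that did not pass (3 and 6, camera adjusted p = 0.25). ANKRD1 (1.55 ± 0.43) was higher. Matrix proteases had 2 rises, 1 fall and 24 that did not pass (5 and 4, camera adjusted p = 0.55). ADAM19 (-1.19 ± 0.19) fell. WNT targets had 0 rises, 3 falls and 7 that did not pass (0 and 3, camera adjusted p = 0.38). DKK1 (-0.59 ± 0.09) was lower. TGF-beta targets had 2 rises, 1 fall and 19 that did not pass (2 and 1, camera adjusted p = 0.67). LTBP2 (-1.16 ± 0.13) was lower. Heat shock proteins had 2 rises, 4 falls and 15 that did not pass (4 and 4, camera adjusted p = 0.95). HSPB8 (1.74 ± 0.29) rose. Mitochondrial genome transcripts had 0 rises, 0 falls and 13 that did not pass (0 and 0, camera adjusted p = 0.23) and passed downward without WT 1 (0.02). Histones had 4 rises, 0 falls and 25 that did not pass (4 and 0, camera adjusted p = 0.38), fibroblast markers 0 rises, 1 fall and 8 that did not pass (0 and 1, camera adjusted p = 0.17) and endothelial markers 0 rises, 1 fall and 6 that did not pass (0 and 1, camera adjusted p = 0.93). EGFL7 (-0.81 ± 0.25) was lower. Median and mean differed in sign for MAPK output (-0.03 and 0.18), VEGF (0.01 and -0.02), histones (0.04 and -0.03) and endothelial markers (-0.01 and 0.22). The camera direction was Up for the last 3 and Down for MAPK output, WNT targets (0.03 and 0.16) and heat shock proteins (0.04 and 0.17).

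**Figure D3:**
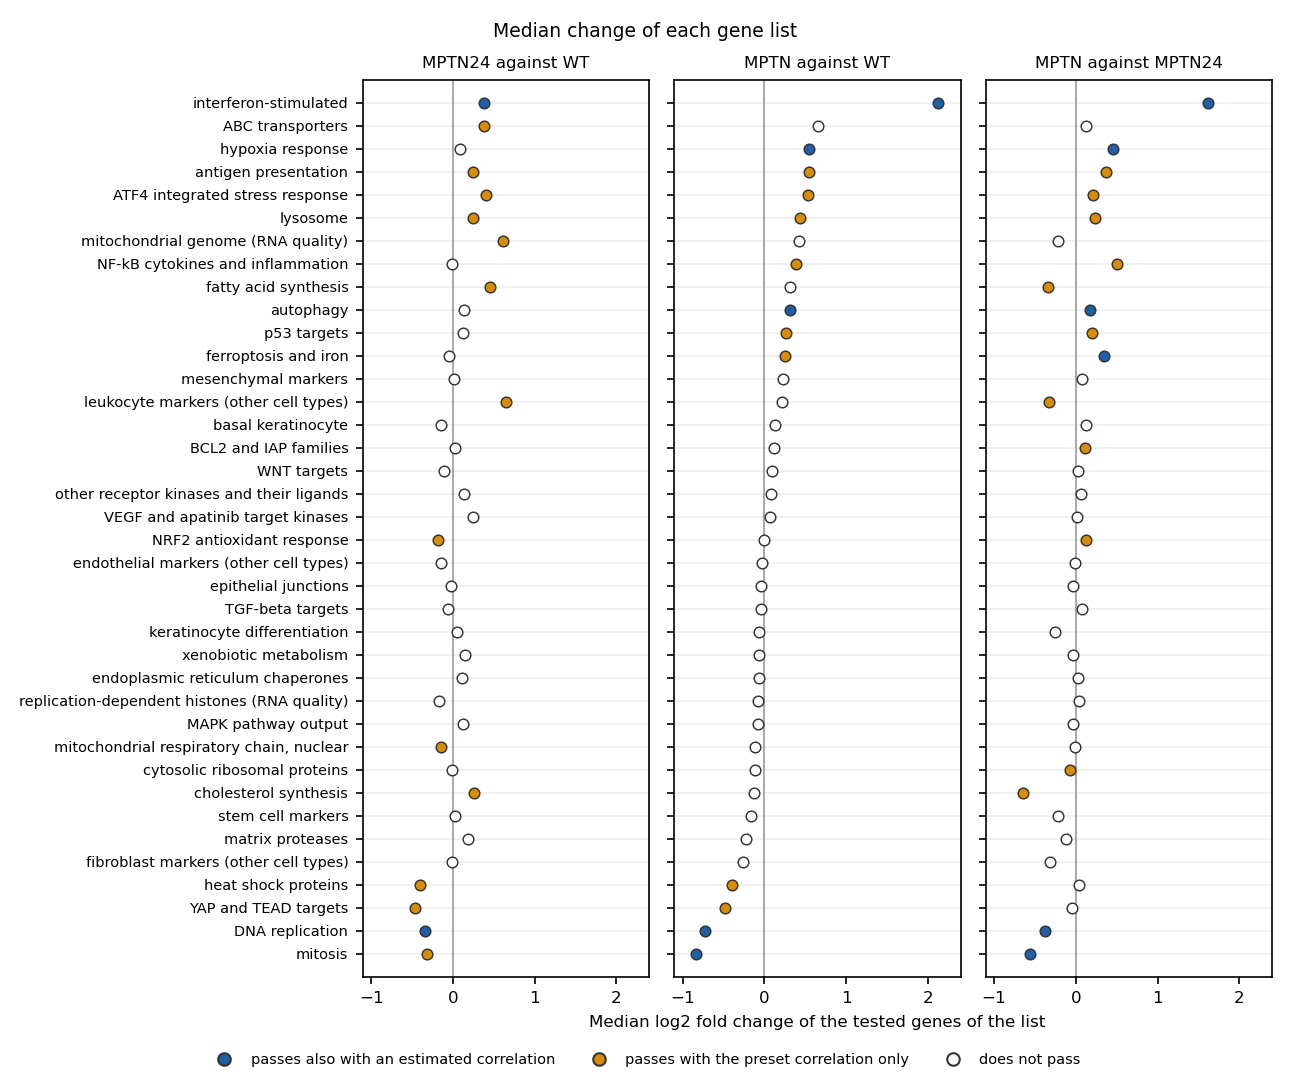
Median log2 change of each of the 38 lists in the 3 comparisons, blue where the call holds with an estimated correlation and orange where it holds only with the preset one. The interferon-stimulated list was at 2.12 in MPTN against WT and at 0.38 in MPTN24 against WT.

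Genes fixed in advance because of the drug were read in all 3 comparisons. KDR, the main target of apatinib, had 0 counts in all 9 libraries. VEGFA (ENSG00000112715, chromosome 6, 43770184 to 43786487), its ligand, rose from 83 ± 6.8 CPM in WT to 143 ± 6.8 CPM in MPTN24 (log2 change 0.78 ± 0.1, edgeR adjusted p = 0.00038) and 161 ± 19 CPM in MPTN (log2 change 0.96 ± 0.11, edgeR adjusted p = 1.5e-05). KIT (ENSG00000157404, chromosome 4, 54657918 to 54740715), a receptor kinase, was at 0.375 ± 0.15 CPM, 0.163 ± 0.18 CPM and 0.187 ± 0.092 CPM in WT, MPTN24 and MPTN (-1.18 ± 0.97 and -1 ± 0.96 against WT, 0.18 ± 0.98 against MPTN24), and RET (ENSG00000165731, chromosome 10, 43077064 to 43130351) at 3.66 ± 0.38 CPM, 4.79 ± 0.63 CPM and 4.12 ± 0.52 CPM (0.39 ± 0.19, 0.17 ± 0.19 and -0.22 ± 0.19), with no call. KIT was at -2.34 against WT and 1.35 against MPTN24 without MPTN24 2. EGFR (ENSG00000146648, chromosome 7, 55019017 to 55211628), the epidermal growth factor receptor, was at 995 ± 130 CPM, 927 ± 58 CPM and 1060 ± 180 CPM without a call (-0.1 ± 0.13, 0.1 ± 0.13 and 0.2 ± 0.13), though with GC offsets it passed in MPTN against WT (0.0087) and MPTN24 (0.012). AXL (ENSG00000167601, chromosome 19, 41219223 to 41261766), a kinase linked to drug tolerance, fell in MPTN to 408 ± 14 CPM from 565 ± 95 CPM in WT (log2 change -0.47 ± 0.12, edgeR adjusted p = 0.006) and 593 ± 46 CPM in MPTN24 (log2 change -0.54 ± 0.12, edgeR adjusted p = 0.0072), and at 24 h its value was 0.07 ± 0.12. ABCB1, the drug exporter P-glycoprotein, had 0, 12 and 17 counts in the MPTN24 libraries, 0 in WT and 9 in MPTN 1 alone, and ABCG2 (ENSG00000118777, chromosome 4, 88090150 to 88231628), another exporter, fell in MPTN to 21.3 ± 1.5 CPM from 31.3 ± 2.1 CPM (log2 change -0.56 ± 0.1, edgeR adjusted p = 0.00095). The fall of ABCG2 at 24 h (log2 change -0.32 ± 0.1, edgeR adjusted p = 0.041) was lost without WT 2 (0.098), WT 3 (0.13), MPTN24 1 (0.089), MPTN24 2 (0.11), MPTN24 3 (0.14), MPTN 1 (0.056) or MPTN 2 (0.058), with upper-quartile normalization (0.087), with a replicate block (0.054), with only the 2 groups (0.059), with GC offsets (0.43) and with limma on log2 of FPKM plus 0.1 (0.26) or 1 (0.25).

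The remaining fixed genes mark growth, cell state and immune evasion. VIM (ENSG00000026025, chromosome 10, 17228241 to 17237593), an intermediate filament of mesenchymal cells, rose to 930 ± 4.9 CPM in MPTN24 (log2 change 0.62 ± 0.11, edgeR adjusted p = 0.0022) and 1070 ± 73 CPM in MPTN (log2 change 0.82 ± 0.11, edgeR adjusted p = 9.8e-05) from 607 ± 99 CPM. CDH1 (ENSG00000039068, chromosome 16, 68737292 to 68835541), E-cadherin, was at 127 ± 11 CPM, 140 ± 3 CPM and 145 ± 21 CPM (0.14 ± 0.11, 0.19 ± 0.11 and 0.05 ± 0.11); against WT it passed in MPTN without MPTN 3 (0.025) and with GC offsets (0.016). CD274 (ENSG00000120217, chromosome 9, 5450503 to 5470566), the immune checkpoint ligand PD-L1, rose in MPTN (16.7 ± 1.7 CPM against 9.99 ± 3.8 CPM, log2 change 0.74 ± 0.2, edgeR adjusted p = 0.0099), while MPTN24 was at 11 ± 0.29 CPM (0.14 ± 0.2 against WT). Without WT 1 CD274 also passed at 24 h (log2 change 0.49, adjusted p = 0.014) and in MPTN against MPTN24 (0.0021, against 0.058 in the full set). The latter also passed without WT 2 (0.0498) or WT 3 (0.033), with a replicate block (0.032), the stricter filter (0.046), only the 2 groups (0.0022), counts divided by 4 (0.044) and DESeq2 (0.026). MKI67 at 24 h (log2 change -0.59 ± 0.2, edgeR adjusted p = 0.055) passed without WT 3 (0.0086), MPTN 1 (0.043) or MPTN 3 (0.023), with a replicate block (0.038), with only the 2 groups (0.033), with GC offsets (0.018) and with DESeq2 (0.0076). Differences between MPTN and MPTN24 were 0.2 ± 0.11 for VIM, 0.18 ± 0.1 for VEGFA, which passed with GC offsets (0.015), and -0.24 ± 0.1 for ABCG2.

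MPTN24 and MPTN were compared with the same WT libraries, and 3 cannot be split, so part of any likeness may come from shared controls. Both rose for 1428 genes, where 346 would be met if the calls were independent, both fell for 1460 (371), and 48 moved in opposite directions (717). Across genes, which are not independent, the log2 changes correlated at r = 0.56. Data simulated with no effect in either group gave 0.49 (0.45 to 0.56, 20 simulations), no baseline for r or signs where groups differ. The covariance was 0.415 against 0.0949 simulated (0.0847 to 0.115). The difference of 0.32 may partly be spread of WT, which varied most. Signs matched in 75.8% of genes against 66.6% (65.9% to 67.6%). Without WT 3 the correlation was 0.66, and without MPTN24 1, 2 or 3 it was 0.47, 0.45 and 0.48. Genes such as OASL, VIM, VEGFA and SREBF1 rose in both, and MCM10, KIF11, HSP90AA1 and F3 (log2 change -0.83 ± 0.1 in MPTN) fell in both.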

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

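GC content and length offsets, counts divided by 4 and list counts were chosen after results had been seen. The other alternatives were fixed before the data were examined. Of 114 named-gene calls, 96 kept their call and direction in every setting without a minimum fold, 18 lost the call in at least 1, and 0 turned over with a call. With a minimum estimated 2-fold change and the same test, the genes higher and lower were 378 and 143 in MPTN24 against WT, 1040 and 409 in MPTN against WT, and 368 and 134 in MPTN against MPTN24. With limma on log2(FPKM + 0.1) and on log2(FPKM + 1) the genes lower were 909 and 902, 1782 and 1778, and 573 and 566; the cause was not tested. Leaving out each library in turn, genes higher and lower ranged over 1022 to 2286 and 935 to 2535, 2468 to 3251 and 2441 to 3307, and 741 to 1860 and 569 to 1732. Among lists without a call, those whose counts moved by over 1.5 times and at least 2 genes without WT 1 then had these rises and falls. In MPTN24 against WT they were other receptor kinases 8 and 5, MAPK output 4 and 6, basal keratinocyte 7 and 8, autophagy 5 and 4, chaperones 7 and 1, NF-kB 15 and 6, xenobiotic 3 and 6, stem cell 1 and 5, matrix proteases 13 and 5. In MPTN against WT they were MAPK output 3 and 6, keratinocyte differentiation 2 and 3, cholesterol synthesis 2 and 14, chaperones 7 and 0, xenobiotic 7 and 9, stem cell 2 and 5, TGF-beta targets 6 and 8, mitochondrial genome 9 and 1. In MPTN against MPTN24 they were other receptor kinases 5 and 7, MAPK output 4 and 3, mesenchymal markers 6 and 6, keratinocyte differentiation 1 and 6, basal keratinocyte 6 and 3, chaperones 3 and 5, ABC transporters 5 and 0, xenobiotic 3 and 5, matrix proteases 6 and 9, TGF-beta targets 4 and 2, heat shock proteins 5 and 5. The number of lists lower in MPTN against WT ranged over 4 to 7, and the correlation of the MPTN24 and MPTN changes over 0.446 to 0.66. With an estimated correlation the lists higher and lower were 1 and 1, 3 and 2, and 4 and 2, and with fry 14 lists were higher in MPTN against WT. With the replicate number as a replicate block the genes higher and lower were 1951 and 2036, 3157 and 3026, and 1330 and 1173. Libraries with the same number in different groups had residual correlations of -0.028 to 0.07, and those with other numbers -0.062 to 0.06, so the numbers gave no sign of pairing.

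Values that turned over had no call in either setting. Over the left-out libraries, log2 changes ranged over -0.048 to 0.485 for CD274 and 0 to 0.217 for AXL in MPTN24 against WT, -0.002 to 0.233 for EGFR in MPTN against WT, and -0.021 to 0.166 for CDH1 and -0.391 to 1.352 for KIT in MPTN against MPTN24. Adjusted p of lists whose direction turned over ranged as follows in MPTN24 against WT: other receptor kinases 0.79 to 0.99, MAPK output 0.19 to 0.96, basal keratinocyte 0.68 to 0.98, NF-kB 0.11 to 0.66, stem cell 0.2 to 0.99, BCL2 and IAP 0.83 to 0.97 and endothelial 0.79 to 0.99. In MPTN against WT they were MAPK output 0.44 to 1, keratinocyte differentiation 0.88 to 0.99, NRF2 0.66 to 0.98, xenobiotic 0.31 to 0.97, matrix proteases 0.73 to 0.98, TGF-beta 0.68 to 0.98 and endothelial 0.92 to 0.99. In MPTN against MPTN24 they were MAPK output 0.73 to 1, chaperones 0.68 to 0.99, respiratory chain 0.035 to 0.95, heat shock 0.85 to 1 and endothelial 0.72 to 0.95. With GC content and length offsets, AXL at 24 h was at -0.052, and lists that turned over were other receptor kinases (0.97), basal keratinocyte (0.62) and BCL2 (0.84) at 24 h, keratinocyte differentiation (0.68), leukocyte (0.55) and endothelial (0.86) in MPTN against WT, and MAPK output (0.78) in MPTN against MPTN24. With no filter these were fibroblast at 24 h (0.75), endothelial in MPTN against WT (0.83) and MAPK output in MPTN against MPTN24 (0.99). MAPK output in MPTN against MPTN24 also turned over with fry (0.88) and with counts divided by 4 (1), and heat shock with fry (0.92); the cause was not tested.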

Other observations

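The genes, windows and tests in this part were chosen only after the result was seen, except the regroupings and splits and, for WT 1, the mislabelling and GC tests. In MPTN the innate RNA sensors DDX58 (4.12-fold), DHX58 (4.94-fold) and IFIH1 (2.08-fold) were higher than in WT, as were the complement genes C1R (2.57-fold) and C1S (2.64-fold). The neural adhesion gene NCAM1 was 22.5-fold higher, the lipopolysaccharide receptor TLR4 15.7-fold, and the clock transcription factor NPAS2 14.7-fold.

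Interferon-stimulated genes were higher in MPTN, with a list median of 2.12 (quartiles 1.04 and 3.42). Leukocyte RNA is argued against by the leukocyte markers, whose median log2 change was 0.22 (quartiles -0.28 and 0.74), and GC content and length bias by a list median of 2.17 with offsets. Interferon gamma signalling is argued against by 6 class II genes, at a median log2 change of 0.56 (quartiles 0.44 and 0.7). However, HLA-DRB1 (log2 change 1.86) and CD74 (0.66) rose, and HLA-DMA (-0.58) and HLA-DMB (0.42) had few counts. Interferon beta and lambda made in the cultures remain possible, as the lowest count of IFNB1 or IFNL1 in an MPTN library was 132. What set off these genes, and whether the drug was present at harvest, stays open.

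WT 1 differed from WT 2 and WT 3 by 2-fold or more in 102 of 9170 genes, against 20 between WT 2 and WT 3. A mislabelled sample is argued against because its median position toward MPTN24 was 0.35, where 1 would be MPTN24 itself. GC content and length offsets removed 12% of the variance. MPTN24 RNA mixed into WT 1 is argued against by 63.7% of the 102 genes, which lay outside the range from WT 2 and WT 3 to MPTN24. A difference in culture or handling stays possible.

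Among 312 windows of 40 genes, 4 lay above the 95th percentile of the highest window in 1000 shuffles of gene order, 1 on chromosome 7 (107579977 to 128410252, 0.26) and 3 neighbours on the long arm of chromosome 5 (78485215 to 132737638), higher in MPTN than in MPTN24 by a median of 0.29 over 120 genes. The lowest, on chromosomes 14 and 15 (-0.29; -0.24 and -0.26 with offsets), lay beyond any shuffle (-0.28), and all 13 of chromosome 10 were below 0 (-0.26 to -0.04), but only chromosome 5 was followed up. There chance placement is argued against by the shuffles (share 0.001, the smallest possible). With offsets the median was 0.24 and that of a chromosome 2 window 0.25, so GC or length bias stays open. Against WT the windows were lower in MPTN24 (-0.22 to -0.15) and MPTN was at 0.02 to 0.14, but with offsets MPTN was at 0.16 to 0.32, so which group departs from WT is open. A gain or loss of part of any of these chromosomes stays open.

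Exchanging libraries between groups gave 10 splits per comparison, too few for a share under 0.05. The real splits gave 3936, 6187 and 2472 changed genes, and only they reached as many, the highest other being 1. For lists the real splits gave 15, 13 and 17, the highest others 11, 15 and 11, and 1, 3 and 1 splits had as many. For the correlation of the MPTN24 and MPTN changes, 34 of 100 regroupings had an r as high (median 0.485, highest other 0.8). Every regrouping shares a control and mixes groups that differ, so this count does not tell whether the likeness is chance.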
